A study of Danio rerio with 13 samples.

How the data were processed

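The series holds 13 samples of zebrafish heart cells: for each of H3K27me3 and H3K4me3, 3 libraries from uninjured hearts and 3 from hearts 5 days after apex resection, and 1 mixed input DNA sample, which is not used here. Per the labels' protocols, cells from the apical part of the ventricle were enriched for cardiomyocytes on a 10 micrometre mesh. The design text calls the libraries of a group biological replicates, and the p-values rest on 3 per group.

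What was analysed is the authors' comparison of resected with uninjured hearts, 1 table per mark, over 42037 promoter windows. 41998 of them are 4 kb wide, with 2 kb on each side of the centre, and 39 are clipped at the start of a sequence. The submitters' processing notes name BWA, Bowtie2 2.3.2, Picard 2.8.1, SAMtools, bedtools 2.26.0, MACS2 and DESeq2, and the genome builds danRer7, GRCz10 and danRer10, with no role for any of them, so the build of the windows is not stated. Coordinates are counted from 1. Windows carry Ensembl gene IDs and symbols in the deposited tables, and 21868 of the 24438 gene IDs were found in a table of gene names.

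The signal per window is the authors' mean of normalised read counts over the libraries they compared, per the file headers, whose column names are those of a DESeq2 results table. The log2 fold change of resected over uninjured and its standard error, also on the log2 scale, are the authors' values per the file headers. The score used to rank genes is the authors' Wald statistic, which matches the log2 fold change divided by its standard error to within 0.0106. Each p-value was deposited by the authors and matches the two-sided normal p of the Wald statistic to within 0.00205, and the adjusted p-value is theirs too. For H3K4me3 they gave an adjusted p-value to 24913 of 42037 windows, and for H3K27me3 to all 41673 with a read. The sources used here do not give the size factors, read filters or depth of each library. The standard errors of H3K4me3 stop at a ceiling that a normal prior with an SD of 0.603 on the log2 scale would give, and those of H3K27me3 do not, so the H3K4me3 fold changes were taken as shrunken. Undoing that prior multiplies the log2 fold changes of called genes by a median of 1.35. Where the count test fixed before the data were examined could not be run for lack of values per library, the authors' comparison took its place.

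A gene was represented by its window with the highest mean count of the mark, mitochondrial windows were left out of genes, and 10705 genes had more than 1 window. A change was called at the authors' adjusted p under 0.05. For each mark, 22 gene lists fixed before the data were examined were tested with limma's cameraPR on the Wald statistics (two-sided, inter-gene correlation 0.01, Benjamini-Hochberg over the lists). A correlation cannot be estimated without values per library, so 0.05 and 0.1 were tried in its place. Counts adjusted over the list alone used Benjamini-Hochberg on the members' p-values. Medians have 95% bootstrap intervals from 10000 resamples of the genes, which hold no spread between libraries and no correlation between genes. Levels of lists were placed among 10000 random lists of the same size, and medians of Wald statistics among 10000 random lists matched in 20 bins of mean H3K4me3 and 10 bins of mean H3K27me3 within each. The difference between the marks was tested per gene at the window of highest H3K4me3, by a two-sided z test of the difference of the log2 fold changes with their standard errors, Benjamini-Hochberg adjusted. Overlaps were tested with the two-sided Fisher's exact test, adjusted over the 4 pairs of directions, on genes with an adjusted p for H3K4me3. Genes are not independent replicates in these tests. The cameraPR test on deposited statistics, the level-matched lists and the z test were chosen after the tables were seen.

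The lists cover sarcomere, cytoskeleton and cytokinesis, cell junctions, calcium handling, cardiac transcription factors, cell cycle, glycolysis, mitochondrial energy, extracellular matrix, epicardial, endocardial, leukocyte, erythroid and thrombocyte, and fibroblast, smooth muscle and pericyte markers, injury response, Polycomb and Trithorax, Hox, other developmental transcription factors, signalling ligands, skeletal muscle, neuronal and ribosomal protein genes. Of their entries, 1184 matched a symbol of the tables, 19 the gene name table and 7 a RefSeq synonym, and 161 matched none. Where an entry gives several symbols, each one found counts, a choice made after values were seen, and taking the first gave the same numbers of called lists. In the fibroblast, smooth muscle and pericyte list, 17 of 28 members are also in another list.

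Genes were named by a rule fixed before the data were examined. It takes, per mark, the 10 called genes with the largest change in each direction that have a gene symbol other than a clone name, or the 5 with the smallest p per direction where fewer than 5 are called. It adds up to 5 called members with the smallest p of each called list and of the sarcomere and cytoskeleton lists, 2 where none is called, the gene with the highest mean of each mark, and ezh2, eed, suz12a and suz12b. Its condition that all libraries of a group lie on one side of the other group could not be applied. Other genes named as called members of a list or of an overlap were chosen after their values were seen. A few genes that the rule takes are not reported here.

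The list test, the difference test, the matching and the undoing of shrinkage were tested on simulated data. Lists simulated for H3K4me3 over 24416 genes with no shift were called in 0% of cases, and in 8.61% when members were correlated at 0.05. A shift of 1 in the Wald statistics was called in 100% and 95% of cases, and a shift of 0.5 in 72.5% and 60%. The difference test, simulated over 24075 genes, found 55.5% of 200 genes with a log2 difference of 2, with 5.93% of its calls wrong. It found none of 200 genes with a difference of 1, where the share of wrong calls is therefore not informative. The alternatives tried were other thresholds, filters on low counts, all windows of a gene, other windows, ranks, other correlations, removal of the trend with levels, and Wald statistics in place of log2 values. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.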

Results

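Promoter chromatin was profiled in zebrafish hearts by chromatin immunoprecipitation and sequencing (ChIP-seq) of a pair of histone marks. H3K4me3, trimethylation of histone H3 at lysine 4, marks active promoters, and H3K27me3, trimethylation at lysine 27, is laid down by the Polycomb repressive complex PRC2 at silenced promoters. The material was cells from the apical part of the ventricle, enriched for cardiomyocytes on a 10 micrometre mesh. Uninjured hearts were set against hearts taken 5 days after resection of the ventricular apex, an injury that zebrafish repair by growing new muscle. Each mark had 3 libraries per condition, described as biological replicates, which made 12 libraries, and 1 mixed input DNA sample brought the series to 13 samples. The subject the study names is H3K27me3 over the promoters of sarcomere and cytoskeleton genes during regeneration, and the division and wound invasion of cardiomyocytes.

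The authors' comparison of resected with uninjured hearts was given for 42037 promoter windows of 4 kb, assigned to 24438 gene IDs. A gene with several windows was represented by the window with its highest mean count of the mark. The depth of each library is not given in the sources used here, and the authors' mean normalised count per window, over the libraries compared, is the measure of depth. The median window, over all 42037 windows, had a mean of 82.9 for H3K4me3 and 56.1 for H3K27me3. The median standard error of the log2 fold change was 0.28 for H3K4me3 and 0.43 for H3K27me3, which do not show which mark was measured more precisely. The log2 fold changes and standard errors of the 2 marks are not on the same scale, because those of H3K4me3 bear the signs of shrinkage towards 0, and the marks were therefore compared mainly by their Wald statistics, each log2 fold change divided by its standard error.

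H3K27me3 stood highest over the promoters of developmental regulators. The 27 Hox genes, which pattern the body axis, had a median mean count of 154, and the 138 other developmental transcription factors had one of 125. Both medians lay above those of all 10000 random lists of the same size. Neuronal genes came next, then skeletal muscle genes (79.6), cardiac transcription factors (76.8) and developmental signalling ligands (76.6). Sarcomere genes had a median of 66.7, higher than most random lists but only at percentile 61.1 of single genes. Ribosomal protein genes (43.6) and cell cycle genes (49.2) lay below all the random lists. H3K4me3 ranked the groups differently, with medians of 351 at genes for Polycomb and Trithorax proteins, 343 at ribosomal protein genes and 285 at genes of mitochondrial energy metabolism, but 43.0 at Hox genes. The gene with the highest H3K4me3 in the authors' deposited table was anp32a, with a mean count of 1511 and a log2 fold change of -0.02, and for H3K27me3 it was the clone-named gene CABZ01079258.1, with 2712 and 0.10. Means here cover both conditions together, so levels in uninjured hearts alone were not analysed here.

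H3K4me3 fell over the genes of the contractile apparatus after resection and rose over genes of cell division, blood cells and the epicardium. The largest loss was at coro1cb, which encodes an actin-binding coronin (log2 fold change -1.86, SE 0.26, adjusted p = 4.98e-09 in the authors' deposited table). Next came cx41.8, a gap junction connexin, lmod2b, a leiomodin of the thin filament, efnb3b, an ephrin, and the transcription factor gene prox1a, for which the authors' deposited table gives log2 fold changes of -1.65, -1.58, -1.58 and -1.57. The largest gain was at fn1a, which encodes fibronectin (1.84, SE 0.25, adjusted p = 1.9e-09 in the authors' deposited table), ahead of the chemokine receptor gene ccr12a (1.73), rspo3, a secreted amplifier of Wnt signalling (1.71), and g2e3 (1.58). Of 24416 genes with a test, 15351 had an adjusted p, and of these 234 rose by a median log2 of 0.98 and 215 fell by a median of 1.01 on the log2 scale, at the authors' adjusted p under 0.05. In the build of that table, which the sources used here do not state, the coro1cb window lies on chromosome 5 at 31302410 to 31306409 and the fn1a window on chromosome 9 at 15451437 to 15455436. Over all windows the count was 757, with 358 higher and 399 lower, and the lower ones included all 22 windows of the mitochondrial genome.

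Other large losses of H3K4me3 were at genes typical of heart muscle. The authors' deposited table lists -1.53 for cmlc1 and -1.52 for myl7, the genes of cardiac myosin light chains, -1.51 for nppa, which encodes natriuretic peptide A, and -1.50 for vmhcl, a ventricular myosin heavy chain gene. It also fell at nmrk2, a nicotinamide riboside kinase gene (-1.40 in the authors' deposited table). Among the gains in the authors' deposited table were pik3r6a, a regulatory subunit of phosphoinositide 3-kinase (1.43), spi1b, the myeloid transcription factor PU.1 (1.41), the RNA-binding protein gene rbm47 (1.41), slc43a3b (1.38), anln, the cytokinesis scaffold anillin (1.38), and laptm5, a lysosomal protein gene of blood cells (1.38). Their standard errors in the authors' deposited table ranged from 0.26 to 0.29, and each passed the adjusted p of 0.05. The nppa window overlaps a window of another gene, as do those of 82 of the 449 called genes, and signal there cannot be assigned to one gene.

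**Figure D1:**
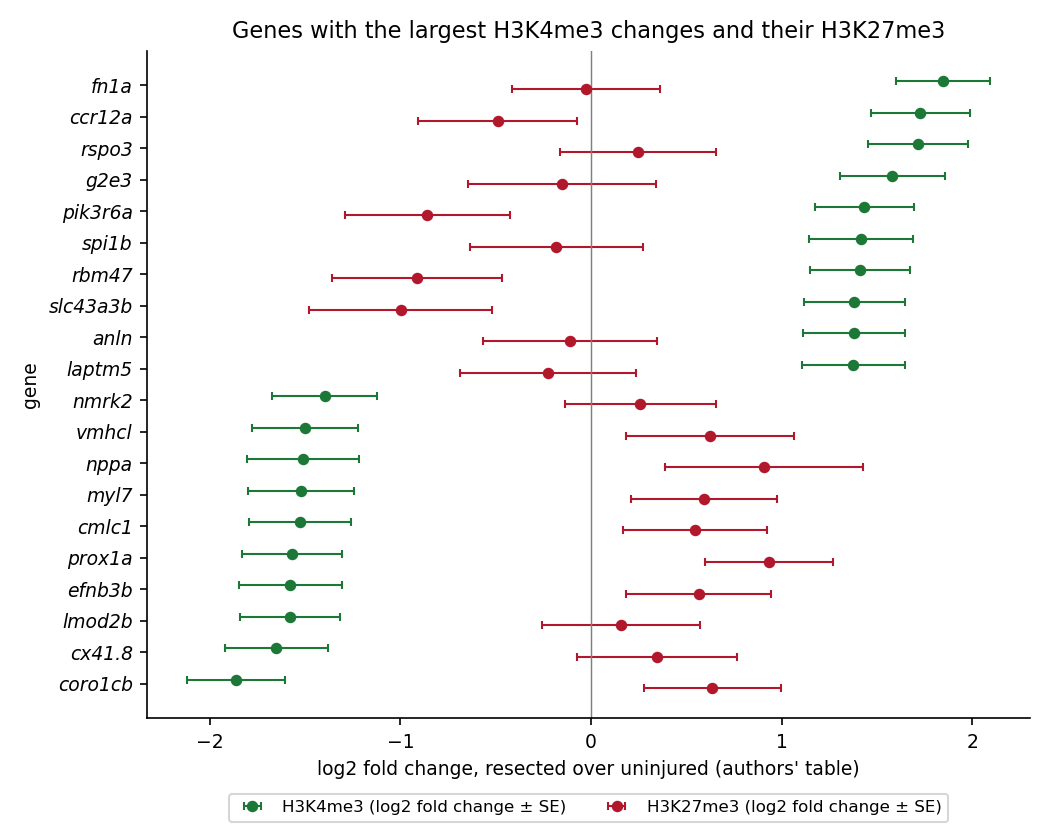
Log2 fold change (resected over uninjured, horizontal axis) of H3K4me3 and H3K27me3 for the 10 called genes with the largest H3K4me3 gain and the 10 with the largest loss, clone-named genes left out, from the authors' deposited table, both at the window of highest H3K4me3, with its standard errors as bars. The H3K4me3 points run from -1.86 at coro1cb to 1.84 at fn1a, and no H3K27me3 value passed the adjusted p of 0.05.

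Sarcomere genes, which build the contractile unit of muscle, lost H3K4me3 as a group. Of 72 measured, 21 fell, 1 rose (TPM1, a tropomyosin gene) and 50 did not pass, against 33 that fell and 1 that rose when adjusted over the list alone. The median Wald statistic was -2.06 (95% interval -2.63 to -1.06), and the list stood apart from all other genes in limma's two-sided cameraPR test (adjusted p = 1.56e-27). Besides lmod2b, cmlc1, myl7 and vmhcl, the genes that fell included synpo2lb (-1.40 in the authors' deposited table), myh7ba, desma, ttn.1, ttn.2, mybpc3 and tnnt2a, which encode a myosin heavy chain, desmin, titins, cardiac myosin-binding protein C and troponin T. In the same samples the leukocyte marker list rose, with a median Wald statistic of 1.62.

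Some cytokinesis genes gained H3K4me3 while the cytoskeleton and cytokinesis list as a whole was not called. Of 87 measured, 6 rose and 1 fell, the same counts as when adjusted over the list alone. The list as a whole did not pass the cameraPR test (median Wald statistic 0.11, adjusted p = 0.223). The 6 were anln, ect2, kif20a and prc1b, whose products act in the cleavage furrow and central spindle, the non-muscle myosin gene myh9a and the keratin gene krt4. In the authors' deposited table their leading values were 1.38 for anln and 1.25 for ect2.

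The loss extended to other cardiomyocyte functions. Of 27 calcium handling and conduction genes, 5 fell (jph1a, kcnh6a, camk2d2, ryr2b and trdn), and 11 did when adjusted over the list alone. These genes couple excitation to contraction, ryr2b encoding the calcium release channel of the sarcoplasmic reticulum, and the median Wald statistic was -1.62 (adjusted p = 3.33e-10). Of 39 cardiac transcription factor genes, 5 fell (nkx2.5, irx1a, tbx5b, irx5a and gata6) and none rose, with 9 falling when adjusted over the list alone (median -1.28, adjusted p = 3.33e-10). For nkx2.5, an early regulator of heart muscle fate, the authors' deposited table gives -1.36, and for tbx5b -1.13. Of 26 genes of cell junctions and the intercalated disc, cx41.8, desma and cx45.6 fell, 4 when adjusted over the list alone (median -0.48, adjusted p = 5.45e-05). Markers of another cell type, the endocardium and endothelium, fell as well, by 5 of 44 genes (prox1a, nfatc1, kdrl, ramp2 and kdr), against 13 that fell and 1 that rose when adjusted over the list alone (median -1.05, adjusted p = 4.13e-09). With no filter on low counts kdrl, ramp2 and kdr were not called. The leukocyte list moved the other way in the same comparison, with a median of 1.62.

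Cell cycle genes gained H3K4me3. Of 62 measured, 17 rose and none fell, and 25 rose when adjusted over the list alone (median Wald statistic 1.82, adjusted p = 1.61e-22). They included ccna2, which encodes cyclin A2, mybl2b, foxm1 and E2F1, transcription factors of the cell cycle, kif11, a spindle motor, and cdk1. The authors' deposited table gives log2 fold changes of 1.32 for ccna2, 1.36 for mybl2b and 1.29 for foxm1. Leukocyte markers rose beside them: 9 of 50 genes, 17 when adjusted over the list alone (median 1.62, adjusted p = 2.02e-17), among them il10ra (1.36 in the authors' deposited table), spi1b, laptm5, ikzf1, cebpa and lcp1. Erythroid and thrombocyte markers followed, with 7 of 36 genes higher, 10 when adjusted over the list alone (median 0.76, adjusted p = 6.87e-06), and 4 of the 7 were the globin genes hbaa1, hbba1, hbaa2 and hbba2, whose windows overlap in pairs.

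Some genes of the epicardium, the outer layer of the heart, and of the extracellular matrix also rose. Of 19 epicardial markers, BNC1, tbx18, wt1a and wt1b rose, the same 4 when adjusted over the list alone (median Wald statistic 0.82, adjusted p = 0.000559). The authors' deposited table gives 1.21 for BNC1, 1.11 for wt1a and 1.04 for tbx18. Of 65 extracellular matrix and remodelling genes, fn1a, vcanb, col12a1a and timp2b rose, encoding fibronectin, versican, a collagen and a metalloproteinase inhibitor, and the count adjusted over the list alone was also 4 (median 0.70, adjusted p = 0.00298). That call was lost with an inter-gene correlation of 0.05 (adjusted p = 0.0993), while the 9 list calls described before it held there and at 0.1. With no filter on low counts timp2b was not called.

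Among the remaining lists, 3 calls were small and lost at a correlation of 0.05. Ribosomal protein genes lay higher with no gene of 83 past the test, over all genes or adjusted over the list alone (median Wald statistic 0.41, adjusted p = 0.0125, and 0.202 at that correlation). Developmental signalling genes lay lower, with fgf3, fgf17 and bmp10 falling among 88, and 3 when adjusted over the list alone (median -0.29, adjusted p = 0.0127, and 0.202). Developmental transcription factors other than Hox lay lower, with prrx1a rising and irx1a, irx2a and irx5a falling among 138, and 1 and 4 when adjusted over the list alone (median -0.19, adjusted p = 0.0436, and 0.346).

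Energy metabolism genes were not called as lists in the main test. The glycolysis list (42 genes, adjusted p = 0.0544) held 1 gene that fell, gapdh, and 2 when adjusted over the list alone, and the mitochondrial energy list (77 genes, adjusted p = 0.0761) held 2 that fell, mb, the myoglobin gene, and ppargc1a, by either count. The injury response list (86 genes, adjusted p = 0.223) had foxm1 higher and nppa, her6 and vegfab lower, and 3 and 6 when adjusted over the list alone. Fibroblast, smooth muscle and pericyte markers (28 genes, adjusted p = 0.484) had tbx18 and prrx1a higher and abcc9 lower, and 2 and 2 when adjusted over the list alone. Of 27 Hox genes hoxb4a rose, by either count (adjusted p = 0.392). No gene passed in the Polycomb and Trithorax list (50 genes, adjusted p = 0.750), the skeletal muscle list (37 genes, adjusted p = 0.750) or the neuronal list (39 genes, adjusted p = 0.596), over all genes or adjusted over the list alone. Of the PRC2 subunits, the authors' deposited table gives 0.20 for ezh2, 0.22 for suz12a, 0.24 for suz12b and -0.25 for eed, and these did not pass.

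**Figure D2:**
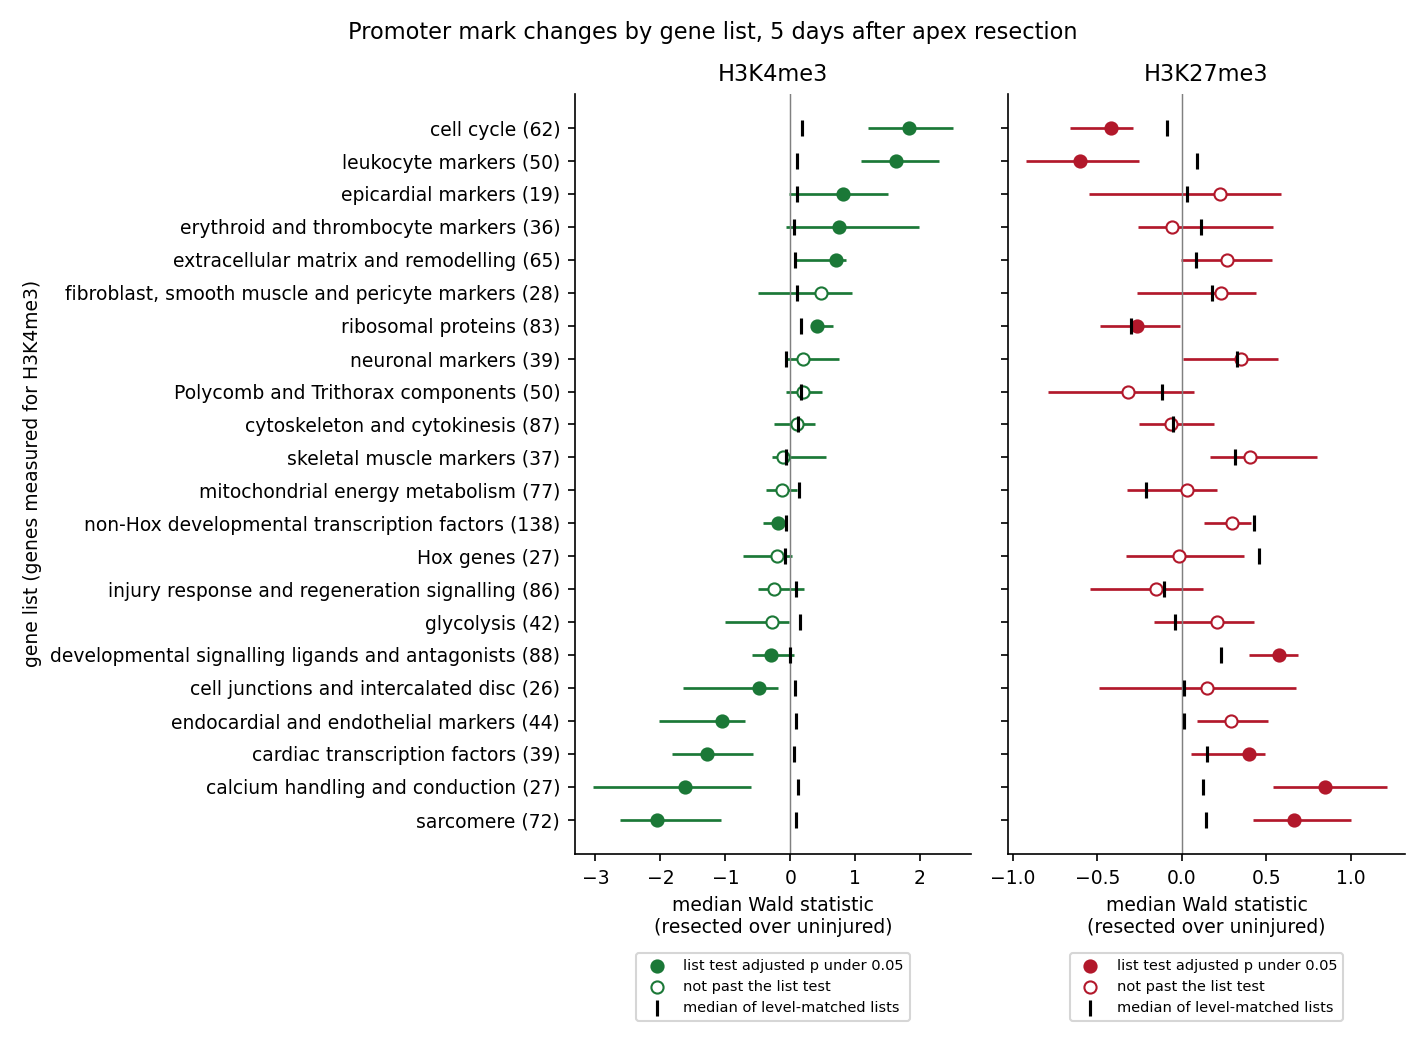
Median Wald statistic (resected over uninjured, horizontal axis) of each of the 22 gene lists for H3K4me3 (left) and H3K27me3 (right), with 95% bootstrap intervals as bars, list test calls as filled points and the median of level-matched random lists as black ticks. Sarcomere genes sit at -2.06 for H3K4me3 and 0.66 for H3K27me3, and leukocyte markers at 1.62 and -0.61.

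H3K27me3 at no single promoter passed the test, but sarcomere genes lay higher and leukocyte markers lower as groups after resection. Of 72 sarcomere genes, 53 had a log2 fold change above 0 and 19 below, with a median Wald statistic of 0.66 (95% interval 0.42 to 1.00) and a median log2 fold change of 0.27. Calcium handling and conduction genes showed the same lean, with 23 of 27 above 0 and a median of 0.85. Leukocyte markers leaned the other way, with 33 of 50 below 0 and a median of -0.61. The cytoskeleton and cytokinesis list was not called in the cameraPR test (40 of 86 above 0, median -0.06, adjusted p = 0.634). It holds cytokinesis genes beside the cytoskeleton genes that the study names, and cytoskeleton genes alone were not tested. In the two-sided cameraPR test the sarcomere, calcium handling and leukocyte lists each had an adjusted p of 0.000108. With an inter-gene correlation of 0.05 these became 0.0576, 0.0193 and 0.0473, and with 0.1 they were 0.340, 0.172 and 0.319.

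Counted gene by gene, 0 of 24075 genes and 0 of 41673 windows had an adjusted p under 0.05 in the authors' deposited table, whose column names are those of DESeq2. At an unadjusted p under 0.05 there were 1310 windows, 415 higher and 895 lower, where chance alone would give 2084. At the median standard error, a 95% interval reaches 0.85 to each side on the log2 scale before any adjustment for the number of windows. The smallest p in the authors' deposited table among named genes was that of gata4, a cardiac transcription factor gene (log2 fold change 1.59, SE 0.42, unadjusted p = 0.000128). It was followed upwards by camsap1a (1.13), tpra (0.88), kcnj8 (1.25) and creb5a (1.40), and downwards the authors' deposited table leads with rfx5 (-2.35), nfe2l3 (-1.93), dnmt3ba (-1.66), hmg20b (-2.51) and cbfb (-1.26).

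Among sarcomere genes the smallest p-values in the authors' deposited table were those of ttn.1, a titin gene (0.77, SE 0.37, unadjusted p = 0.0399), and myh7ba, a myosin heavy chain gene (0.72, SE 0.36, unadjusted p = 0.0451). Of the cytoskeleton list they were those of fblim1 (-0.74, unadjusted p = 0.0303 in the authors' deposited table) and vcla, a vinculin gene (0.78, unadjusted p = 0.0313). Calcium handling was led by cacnb2a, a calcium channel subunit gene (1.07), and jph1a (1.00), and cardiac transcription factors after gata4 by gata6 (1.05 in the authors' deposited table). Among leukocyte markers, lcp1, a leukocyte plastin gene, had -0.80 in the authors' deposited table. No sarcomere, cytoskeleton, calcium handling or leukocyte gene passed when adjusted over the list alone, and in the cardiac transcription factor list gata4 did.

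Another 4 lists were called for H3K27me3, and each call was lost at a correlation of 0.05. Developmental signalling genes lay higher, 65 of 88 above 0 (median Wald statistic 0.58, adjusted p = 0.00119, and 0.158 at that correlation), led by wnt6a and frzb. Cardiac transcription factors lay higher, 27 of 39 above 0 (0.40, adjusted p = 0.0329, and 0.262). Cell cycle genes lay lower, 45 of 62 below 0 (-0.42, adjusted p = 0.00393, and 0.159), led by mcm6 and orc1 of the replication machinery, and ribosomal protein genes did too, 51 of 82 below 0 (-0.26, adjusted p = 0.0371, and 0.343). Apart from gata4, no gene of these lists passed when adjusted over the list alone. The cell cycle and ribosomal protein lists had H3K27me3 levels below all random lists. A lower count there need not be a loss of the mark.

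The remaining lists were not called, with no gene past the test when adjusted over the list alone. Skeletal muscle genes (median Wald statistic 0.40, adjusted p = 0.0589), Polycomb and Trithorax genes (-0.32, adjusted p = 0.0623) and developmental transcription factors other than Hox (0.30, adjusted p = 0.0821) came closest. Endocardial and endothelial markers had a median of 0.29 and neuronal genes one of 0.35, both with an adjusted p of 0.180. Injury response genes (-0.15, adjusted p = 0.264) and extracellular matrix genes (0.27, adjusted p = 0.374) followed. The junction (0.15), glycolysis (0.21), mitochondrial energy (0.03), erythroid and thrombocyte (-0.06) and fibroblast, smooth muscle and pericyte (0.23) lists shared an adjusted p of 0.634, the mitochondrial and erythroid lists having means of the opposite sign to their medians. Epicardial markers (0.23) and Hox genes (-0.02) had one of 0.857. Of the PRC2 subunits, the authors' deposited table gives 0.12 for ezh2, 0.17 for suz12a, -0.04 for suz12b and -0.99 for eed (unadjusted p = 0.0314).

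Genes that lost H3K4me3, as one set, leaned towards higher H3K27me3, and genes that gained it towards lower. Not each list followed this, since extracellular matrix genes (40 of 65 above 0) and epicardial markers (median Wald statistic 0.23) gained H3K4me3 and did not lean towards lower H3K27me3. At 214 genes with lower H3K4me3, with both marks read at the window of highest H3K4me3, 173 had an H3K27me3 log2 fold change above 0 and 41 below, and the median H3K27me3 Wald statistic was 0.76 (95% interval 0.63 to 0.86). Among 10000 random gene lists matched on the levels of both marks, the typical median was -0.03 and none lay higher. At 233 genes with higher H3K4me3, 174 lay below 0 and the median was -0.45 (95% interval -0.64 to -0.32), lower than in all matched lists. These intervals, the matched lists and the overlap tests below treat genes as independent. Correlation between genes, which would widen the intervals, was not allowed for in them. The genes that lost H3K4me3 and had higher H3K27me3 at an unadjusted p under 0.05 numbered 14 where 1.73 would overlap by chance (two-sided Fisher's exact test over 15239 genes, odds ratio 9.58, adjusted p = 7.6e-09). They included the sarcomere genes ttn.1, myh7ba and flnca, the transcription factor genes prox1a, gata6, irx1a and irx2a, and jph1a. In the opposite pairing, 15 genes gained H3K4me3 and had lower H3K27me3 where 6.50 would by chance (odds ratio 2.45, adjusted p = 0.0067), among them cebpa, lcp1, itga4, nuf2 and kif11, though kif11 stands at 0.21 at its window of highest H3K27me3 in the authors' deposited table. Both marks higher held 1 gene against 1.88 by chance (adjusted p = 1), and both lower held 0 against 5.97 (adjusted p = 0.0067).

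**Figure D3:**
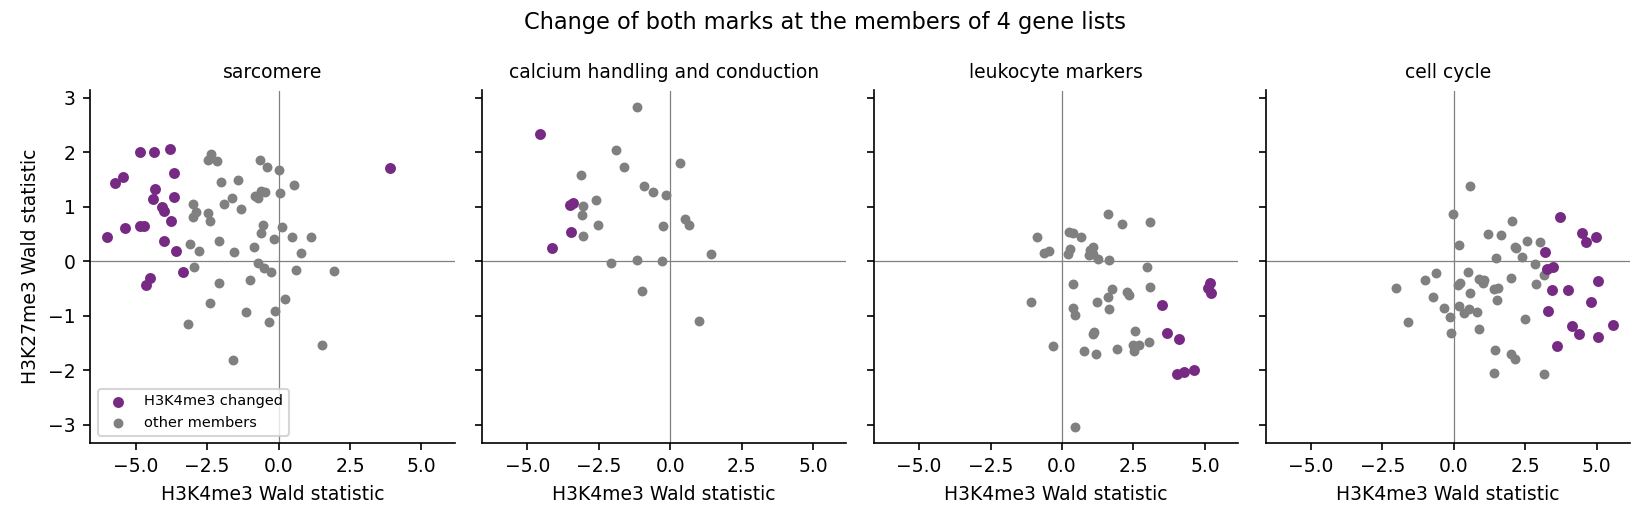
Wald statistic of H3K4me3 (horizontal axis) and of H3K27me3 (vertical axis), resected over uninjured, with 1 point per gene of the sarcomere, calcium handling, leukocyte and cell cycle lists, each mark at its own window, and genes with a called H3K4me3 change in purple. For H3K27me3, 53 of 72 sarcomere genes lie above 0, and 33 of 50 leukocyte markers lie below 0.

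Over all 24075 genes the correlation between the marks was weak, with a Pearson correlation of the log2 fold changes of -0.106 and a Spearman correlation of -0.091 across genes, which are not independent replicates. Only 3.14% of windows had an unadjusted p under 0.05 for H3K27me3. Noise in these values lowers such a correlation, so it does not give the strength of the relation. A direct test of the difference between the marks (a two-sided z test of the log2 fold changes at the same window, Benjamini-Hochberg adjusted) called 37 genes, with H3K27me3 above H3K4me3 at 27 and below at 10. First among them was prox1a, a regulator of lymphatic endothelial and heart muscle development, where the authors' deposited table gives 0.93 for H3K27me3 and -1.57 for H3K4me3 (adjusted p of the difference 9.98e-05). The difference at coro1cb was 0.64 against -1.86 in the authors' deposited table (adjusted p = 0.000172), and irx2a, irx1a and nkx2.5 were also called. In the other direction, pik3r6a had -0.86 against 1.43 in the authors' deposited table, and ccr12a and rbm47 were called too. A call does not require a change of H3K27me3. At fn1a, also called, the authors' deposited table gives -0.03 (SE 0.39) for H3K27me3 against 1.84 for H3K4me3. The test also subtracts log2 fold changes that are not on the same scale. Undoing the inferred shrinkage of the H3K4me3 values raised the count from 37 to 100.

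H3K27me3 changes also went with the levels of both marks at a promoter. In the tenth of genes with the lowest H3K4me3 count, the median H3K27me3 log2 fold change was 0.14, and in the tenth with the highest it was -0.27. The Spearman correlation between the H3K27me3 log2 fold change and the mean H3K4me3 count of the same window was -0.317 over 24075 genes, and that with the mean H3K27me3 count was 0.312, the mean counts of the marks themselves correlating at -0.490. Ribosomal protein genes, among the most active, had a median H3K27me3 log2 fold change of -0.14, and Hox genes one of -0.01. The sarcomere, calcium handling and leukocyte calls were kept after this trend was removed from the Wald statistics (adjusted p = 0.000565, 0.00017 and 1.75e-05), while those of cell cycle (0.0578), signalling (0.0626), cardiac transcription factor (0.0838) and ribosomal protein genes (adjusted p = 0.979) were lost. Hox genes became a call in the lower direction (adjusted p = 0.0463).

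**Figure D4:**
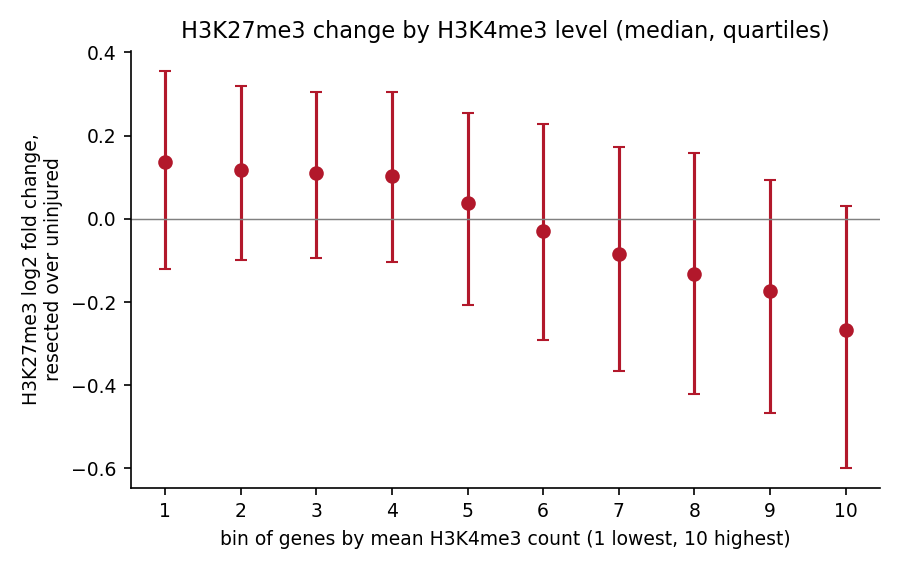
Median H3K27me3 log2 fold change (resected over uninjured, vertical axis, bars from lower to upper quartile) of genes in 10 bins of equal size by mean H3K4me3 count (horizontal axis, bin 1 lowest). The median goes from 0.14 in bin 1 to -0.27 in bin 10.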

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

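The tests of leukocyte H3K27me3 and of low counts against level-matched lists, the difference test between the marks and the values of the mitochondrial windows were chosen after results were seen, and the other tests of explanations after the tables were seen but before the values they measure.

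H3K4me3 fell at cardiomyocyte genes and rose at cell cycle and non-cardiomyocyte genes. If cardiomyocytes had a lower share of the resected samples with every other cell type raised alike, the marker lists would move together, but their median Wald statistics were 1.62 for leukocytes, 0.82 for epicardium, 0.76 for erythroid cells and -1.05 for endocardium, and differed (permutation p = 0.0004 in 100000 resamples). A lower share with leukocytes raised remains possible, since cardiac transcription factors fell with the sarcomere list (median -1.28, 95% interval -1.81 to -0.57), and 45 of 50 leukocyte markers had a log2 fold change above 0 (1.16 at ikzf1 in the authors' deposited table, and 0.91 at cebpa, which has the highest count but a window that another gene's overlaps), although the mesh was meant to enrich cardiomyocytes. Windows with low counts are argued against as the source of the list shifts, because among random lists matched on the levels of both marks the sarcomere list lay at percentile 0 and the leukocyte and cell cycle lists at 100, but for single calls they cannot be told apart, as 22.7% of the 449 called genes (95% interval 18.9 to 26.9) lay above the median mean count of the 15351 genes with an adjusted p, 26 higher and 76 lower. A change of promoter state within cardiomyocytes after injury, which the design names, also stays open and was not tested.

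H3K27me3 lay higher at sarcomere promoters as a group. A trend with the levels of both marks would place the list within the range of level-matched random lists, but its median of 0.66 lay at percentile 100 of 10000, which argues against that trend as the whole cause. An exchange of marks at the same promoters is consistent with the 21 sarcomere genes that lost H3K4me3, of which 19 had H3K27me3 above 0 at the window of highest H3K4me3 (median Wald statistic 1.08, percentile 100 of matched lists), but the other 51 sarcomere genes leaned the same way (median 0.48, 32 above 0, percentile 99.6). A lower share of cardiomyocytes in the resected samples with leukocytes raised may give the same picture, since it predicts the mirror image at leukocyte markers, and their median of -0.61 lay at percentile 0 of matched lists. Both stay open, as no list value here separates them, and the sarcomere call itself ended at an inter-gene correlation of 0.05 (adjusted p = 0.0576, and 0.000108 to 0.340 over the correlations tried). The windows of the mitochondrial genome were lower after resection by a median of 3.88-fold for H3K27me3 and 2.21-fold for H3K4me3. An exchange of marks at sarcomere promoters makes no prediction for them, and whether they follow the share of cardiomyocytes was not tested.

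H3K27me3 lay lower at active promoters after resection, with median log2 fold changes from 0.14 in the tenth of genes with the least H3K4me3 to -0.27 in the tenth with the most. A lower ratio of signal to noise in the H3K27me3 libraries of uninjured hearts could give such a trend, and would put ribosomal protein genes at least 0.1 below the median gene and Hox genes above it. Ribosomal protein genes lay at -0.16 from the median gene (95% interval -0.25 to -0.03) and Hox genes at -0.03 (-0.14 to 0.11), so the first part was met and the second was not seen. The 138 other developmental transcription factors, also high in H3K27me3, had a median log2 fold change of 0.10, against 0.02 for the median gene. Of these, 84 lay above 0 and 54 below, and their median Wald statistic lay at percentile 3.09 of level-matched lists. Against level-matched lists Hox genes lay low (percentile 0.3), which goes against this explanation for Hox genes, but for the active promoters it cannot be told apart from a change in the cells without values per library. Windows of the mitochondrial genome, which has no histones, were lower after resection by a median of 3.88-fold for H3K27me3 and 2.21-fold for H3K4me3. That is the direction of more background in uninjured hearts, but its cause was not tested. No biological explanation of the trend with H3K4me3 level was tested.

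The change differed between the marks at 37 genes, 27 with H3K27me3 above H3K4me3 and 10 below. Such a call can rest on H3K4me3 alone, as at fn1a. The 22 windows of the mitochondrial genome, which has no histones and is outside the comparisons of genes, had a median mean count of 1005 for H3K27me3 and 840 for H3K4me3, against 56.1 and 82.8 in the other windows. Their log2 fold changes in the authors' deposited table ran from -2.09 to -1.74 for H3K27me3, with unadjusted p from 0.00202 to 0.00844 and 0 of 22 called, and from -1.62 to -1.02 for H3K4me3, with 22 of 22 called. As all these windows lie on the mitochondrial genome, they are not independent observations.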

How the results depend on the processing

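The correlations of 0.05 and 0.1, ranks, the median filter on lists, removal of the trend, undoing of shrinkage, Wald statistics in place of log2 values, other windows for the marks, the adjustment redone over the same windows, leaving out mitochondrial or overlapping windows, any window of a gene and the first symbol of an entry were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the tables hold no values per library. For the same reason a refit of counts with limma-voom or the submitters' tool, total-count, median-of-ratios and loess scaling, pseudocounts, input scaling, an estimated correlation, leaving out libraries and other splits of the samples were not run. H3K27me3 calls stayed at 0 genes under each threshold and filter tried. H3K4me3 calls ranged from 630 to 1074 windows and 343 to 659 genes, apart from 397 windows (168 higher, 229 lower) and 214 genes (104 higher, 110 lower) when a log2 change of at least 1 was also required, which by construction takes fewer. Of 66 named H3K4me3 genes that were called, 62 remained with no filter on low counts, and timp2b, kdrl, ramp2 and kdr did not. Of 13 called H3K4me3 lists, 9 were kept in all alternatives. The glycolysis and mitochondrial energy lists were called lower in 3 of 7 (all windows, genes with an adjusted p, trend removed), with a lowest cameraPR adjusted p of 0.0187 and 0.00748. The sarcomere list stayed between an adjusted p of 1.09e-38 and 6.3e-06. The 0.00748 and the 1.09e-38 came with all windows kept, where the windows of a gene count as separate members and p-values can be too small.

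H3K27me3 lists depended more on the settings. From 7 called, the count went to 2 at a correlation of 0.05, 0 at 0.1, 12 with all windows of a gene, 2 among genes at or above the median mean count and 4 with the trend removed, Hox genes among these, and no list was kept in all. With all windows kept, the windows of a gene count as separate members (171 for the 72 sarcomere genes), so p-values there can be too small. The 2 among genes at or above the median mean count were the sarcomere and leukocyte lists. The calcium handling call was lost there (cameraPR adjusted p = 0.0946). The lists not called at first that were called in some alternative were junction, extracellular matrix, Hox, other developmental transcription factor, Polycomb and Trithorax, and skeletal muscle genes. The sarcomere list had an adjusted p of 0.0576 at 0.05 and 0.340 at 0.1, and between 4.57e-08 and 0.0191 elsewhere. The cytoskeleton and cytokinesis list was not called in any alternative for either mark. The difference between the marks went from 37 to 100 genes with the shrinkage undone, which enlarges the H3K4me3 changes. The Pearson correlation of the marks, -0.106, became -0.204 among genes above the median level of both, -0.123 at the window of highest H3K4me3 and -0.121 with Wald statistics, and also -0.121 with Wald statistics at the window of highest H3K4me3 after the trend with levels was removed. Apart from those whose construction is named, the cause of these shifts was not tested. No called list changed direction, but lists not called in either setting did. For H3K27me3, reversed lists among genes at or above the median mean count were junction and cytoskeleton (adjusted p = 0.966), epicardial and fibroblast (0.789) and mitochondrial energy genes (0.834). With the trend removed they were cytoskeleton, fibroblast and neuronal (0.979), mitochondrial energy (0.436) and other developmental transcription factor genes (0.398). For H3K4me3 they were Hox (0.476) and neuronal genes (0.0708) among genes with an adjusted p, and Polycomb and Trithorax and skeletal muscle genes (0.924) with the trend removed. The median standard error of H3K27me3 was 0.43 on the log2 scale, before any adjustment.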

Other observations

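The genes described here are called for H3K4me3 and outside the lists, and they were picked after their values were seen. H3K4me3 rose at itga4, the integrin alpha 4 gene, by a log2 fold change of 1.16 in the authors' deposited table, and at lyn, a Src-family kinase gene of blood cells, by 1.34. Both differed between the marks, the authors' deposited table giving -1.07 and -0.59 for H3K27me3 at the window of highest H3K4me3. It also rose at dre-mir-21-1, a gene of the injury-associated microRNA miR-21 (0.78 in the authors' deposited table). Among the losses were hsd11b2, an enzyme gene of glucocorticoid inactivation (-1.33), the sodium pump subunit gene atp1a3b (-1.28) and tmem178 (-1.29), all from the authors' deposited table.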
